A study of Arabidopsis thaliana with 4 samples.

How the data were processed

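RNA sequencing of whole siliques 4 days after pollination gave 1 library for each of 4 genotypes, WT, hda6, hda9 and hda6 hda9. Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff and the TAIR10 genome were used. Which tool made which column, and whether reads were counted by strand, is not given in the sources used here. The authors deposited 3 tables, each setting WT beside a mutant, with 27684 features. The WT columns were identical in the 3 tables. Per the file headers, the tables hold estimated counts per gene, which need not be whole (2.76% of WT values were not). Per the file headers, they also hold FPKM values (fragments scaled to gene length and library size), in which the authors wrote 0.001 where the value was 0, and this was set back to 0. The authors' deposited log2 fold was found to equal the log2 ratio of the deposited FPKM values. The deposited tables also give the authors' p-value and false discovery rate per gene, and their test is not given in the sources used here. The mutant columns were headed hda6 in all 3 tables, and each was assigned to a mutant by the sheet title.

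From the FPKM values, log2(FPKM + 1) differences were computed for each mutant against WT and for the double mutant against each single mutant. A gene was counted where at least 1 of the 2 libraries had an FPKM of 1 or more, and the threshold was 2-fold. With 1 library per genotype no test was run and no p-value was computed. Ratios of rounded counts scaled to the library totals (CPM) were given exact 95% intervals (conditional binomial, Clopper-Pearson), and where a count was 0 the fold was bounded with a floor of 3 counts per library, which is 0.264 CPM in WT, 0.235 in hda6, 0.287 in hda9 and 0.252 in hda6 hda9. Reads are not shown to be independent molecules, so intervals and floors cover counting error only.

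Before the data were examined, 36 gene lists were fixed by symbol, of which 34 had at least 5 measured members. After the tables were seen, 11 matches were left out because their annotation showed another gene, a choice made from the annotation and not from the values. The median of each list was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries. The rule for named genes was fixed beforehand too. It took HDA6 and HDA9, the 8 largest folds in each direction against WT and the 4 largest for the double mutant against each single mutant (FPKM of 5 or more in 1 of the 2 libraries, organellar genes left out), up to 4 members per list with the largest fold in the double mutant, and the reference genes. Neighbours named beside a gene, and AT2G24945, were chosen after their values were seen. The stress genes HAI1, P5CSA, DREB2A and ERD7 also lie outside the rule and were named for their folds. Near-identical copies of these stress genes were not sought.

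Overlaps between mutants, and the classes of genes in the double mutant, were set beside 100 simulated sets of unchanged libraries, with a spread per expression bin from the median absolute deviation of the mutant and WT differences. The design did not fix the shape of the noise. Heavier-tailed noise was run first, normal noise was then added, and both are reported. The alternatives tried were pseudocounts of 0.1 and 5, an FPKM minimum of 5, no filter, 2 other scalings, the authors' fold, CPM, and the authors' false discovery rate. Added after seeing the data were an interval of the count ratio that excludes 1, and leaving out overlapping genes or XLOC loci, which are 268 loci added to the annotated genes.

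Gene names came from the tables and from the RefSeq annotation of TAIR10.1, in which 26719 of the IDs were found. The builds differ in name, so it was used only for names, neighbouring and overlapping genes, and copies, and no coordinates are given. Near-identical copies were sought with BLAST 2.17.0 (95% identity over 50% of the gene). The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting of 2-fold genes was tested on simulated data, with 200 of 27684 genes changed 4-fold, taken from genes with a mean FPKM of 5 or more. The simulated counts held counting error only (Poisson) and no other difference between libraries. The numbers of unchanged genes called therefore do not measure false calls in the real libraries. For hda6 against WT it recovered 100% of those higher and 99% of those lower, with 15 of 18582 unchanged genes called, and for hda9 against WT 100% of both, with 30 of 18595 called. For hda6 hda9 it recovered 100% of both in each comparison, with 16 of 18579 called against WT, 13 of 18573 against hda6 and 20 of 18597 against hda9.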

Results

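Transcript levels were measured by RNA sequencing in siliques, the seed-bearing fruits of Arabidopsis thaliana, collected 4 days after pollination. There were 4 genotypes with 1 library each: wild type (WT), hda6, hda9 and the hda6 hda9 double mutant. HDA6 and HDA9 encode histone deacetylases, enzymes that remove acetyl groups from histones. The library totals were 11362313 counts in WT, 12758490 in hda6, 10460765 in hda9 and 11928352 in hda6 hda9. With 1 library per genotype there was no spread between replicates and no test of a difference between genotypes. Folds are on the log2(FPKM + 1) scale, and each describes these libraries. Ratios of counts normalised to library totals are given with exact 95% intervals, which cover counting error only. The mutant columns of all 3 deposited tables carry the heading hda6, and the mutant of each table was taken from the title of the sheet, so every direction below rests on those titles.

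The targeted genes were examined first. HDA9 (AT3G44680) had 273 counts in WT, 261 in hda6, 14 in hda9 and 26 in hda6 hda9. Its count ratio to WT was 0.0557 (0.0301 to 0.0951) in hda9 and 0.0907 (0.0582 to 0.136) in hda6 hda9, against 0.851 (0.716 to 1.01) in hda6. HDA6 (AT5G63110) had 347 counts in WT, 379 in hda6, 277 in hda9 and 320 in hda6 hda9. Its ratio in hda6 was 0.973 (0.839 to 1.13), so its transcript level does not check the hda6 label. HDA6 overlaps AT5G63100, and without strand the reads of the pair are not separable.

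The first comparison set hda6 beside WT, to see which genes differed where HDA6 was mutated. The genes with the largest folds were nearly silent in WT and well expressed in hda6. AT5G26270 had 0 counts in WT and 1529 in hda6, at least 454-fold higher. AT2G05642, annotated as a nucleic acid-binding protein, had 0 and 910 counts, at least 270-fold higher, and AT5G45570, an Ulp1 protease family member, had 0 and 1235, at least 367-fold higher. The locus XLOC_007305, annotated as an En/Spm-like transposon protein, had 2 counts in WT and 2428 in hda6. AT3G54730 had 1 and 1031 counts and AT2G19850 had 4 and 582, and these genes share near-identical sequence with each other and with ATOFP9, so their reads cannot be assigned with certainty. AT3G01345 had 27 and 2855 counts, and AT5G45095 had 10 and 1157. ROS1 (AT2G36490), a DNA glycosylase that removes methylated cytosine, was lower, with 2093 counts in WT and 656 in hda6, a ratio of 0.279 (0.255 to 0.305). LSU1 (AT3G49580), a gene of the low-sulfur response, had 77 and 12 counts. PUX9 (AT4G00752) had 207 counts in WT and 0 in hda6, but it overlaps AT4G00750, and the counts of the pair, which are not separable without strand, summed to 1847 and 469. AT5G63250 had 85 and 9 counts, AT5G38160 had 55 and 3, AT5G38170 had 49 and 7, AT5G05030 had 119 and 16, and AT3G24068 had 120 and 29. AT5G52550 had 192 and 0, but its counts and those of the upstream reading frame CPuORF14 listed beside it summed to 387 in WT and 445 in hda6.

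Among gene lists, jasmonate genes were lower in hda6, with a median log2 fold of -0.36 over 19 genes, and the list stood at percentile 0 of 10000 random lists matched on expression. The repressor gene TIFY9 had a log2 fold of -1.05. Cell cycle genes had a median of -0.31 over 40 genes (percentile 0), with CYCD3-2 at -0.61. Xyloglucan endotransglucosylase/hydrolase genes, which remodel cell walls, had a median of 0.32 over 25 genes (percentile 100), and 3 were at least 2-fold higher, among them XTH17 at 1.77 and XTH14 at 1.38. Flavonoid and anthocyanin genes had a median of 0.29 over 16 genes (percentile 99.96), with the regulator MYB90 at 1.48. The cold-responsive genes COR15A and COR15B had log2 folds of 1.03 and 1.18, KIN2 had 458 counts in WT and 1110 in hda6, while HAI1, P5CSA and DREB2A, of the same list of stress genes, were at -1.51, -1.12 and -1.11. That list had a median of 0.08 over 20 genes (percentile 93.6), with 5 at least 2-fold higher and 3 lower. Of the auxin lists, SAUR genes had a median of 0.18 over 46 genes (percentile 99.79) and no member at least 2-fold different, transport genes 0.21 over 18 (percentile 99.97), and Aux/IAA genes 0.04 over 24 (percentile 83.85). Of 19053 genes compared, 416 were at least 2-fold higher and 139 lower. These counts depended on the pseudocount, with 787 higher and 324 lower at a pseudocount of 0.1, and 95 and 23 at 5.

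The next comparison set hda9 beside WT. Genes of jasmonate signalling and synthesis were higher, with a median log2 fold of 0.61 over 20 genes (percentile 100), and 5 were at least 2-fold higher. TIFY9 had 461 counts in WT and 1273 in hda9, a ratio of 3 (2.69 to 3.34). TIFY 5B was at 1.25 and OPR3, an enzyme of jasmonate synthesis, at 0.74. Defence genes had a median of 0.68 over 13 genes (percentile 100), with the transcription factor WRKY18 at a ratio of 2.59 (2.45 to 2.75) and WRKY53 at a log2 fold of 1.13. WRKY53 overlaps HMGB6, and the sums of that pair were 796 and 907. Heat shock genes had a median of 0.41 over 9 genes (percentile 99.96), with HSFA2, a heat stress transcription factor, at a ratio of 4.34 (3.41 to 5.59). Pollen genes had a median of 0.62 over 18 genes (percentile 100) in the same library, with the pectinesterase genes PME5 at 369 and 756 counts and PME4 at 221 and 476, which is given here because pollen transcripts differed alongside the jasmonate, defence and heat shock genes. Stress genes had a median of 0.44 over 20 genes (percentile 100), with 2 at least 2-fold higher, KIN1 at 1.09 and ERD7 at 1.06.

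Some groups were lower in hda9. Secondary wall and dehiscence genes had a median of -0.39 over 22 genes (percentile 0), with the cellulose synthase genes CESA4 at a ratio of 0.506 (0.476 to 0.537) and CESA7 at 0.5 (0.465 to 0.537), while none was at least 2-fold lower on the log2(FPKM + 1) scale. Flavonoid and anthocyanin genes had a median of -0.41 over 16 genes (percentile 0.03). GH3 genes, which conjugate auxin and other acids to amino acids, were higher, with a median of 0.69 over 8 genes (percentile 100), GH3.5 at 0.70 and GH3.12 at -1.69. Flowering-time genes had a median of 0.13 over 14 genes (percentile 96.93), inside the middle 95% of random lists (-0.27 to 0.14). None was at least 2-fold higher, with SPL4 at 0.79 and SOC1 at 0.78, and 2 were lower, the MADS-box genes MAF4 and MAF5 at -1.55 and -1.56. AT5G16350, a member of the wax ester synthase-like family, had 680 counts in WT and 52 in hda9, a ratio of 0.0831 (0.0614 to 0.11), and its neighbour AAE5 had 540 and 57, a ratio of 0.115 (0.0857 to 0.151). AT5G16350 and AAE5 had 567 and 448 counts in hda6, and 380 and 418 in hda6 hda9, where HDA9 was mutated too. Such low values were therefore seen in the hda9 library only. AT5G63250 had 85 counts in WT and 0 in hda9, at least 26.1-fold lower, and AT5G38160 had 55 and 0, at least 16.9-fold lower. AT1G43667 had 63 and 6 counts.

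MRD1 had 0 counts in WT and 180 in hda9, at least 65.1-fold higher, and was also at 228 in hda6 and 207 in hda6 hda9. It overlaps HEI10, and the counts of the pair summed to 17 in WT, 284 in hda6, 222 in hda9 and 264 in hda6 hda9. FAMT, a methyltransferase gene, had 28 counts in WT and 212 in hda9, PCR2 had 69 and 334, and AT5G60610 had 7 and 76. In hda6 and hda6 hda9 the counts were 65 and 61 for FAMT, 75 and 129 for PCR2, and 112 and 116 for AT5G60610. AT2G41231 had 0 counts in WT and 50 in hda9, but it overlaps ORS1 and the sums of the pair were 284 and 251. Several of the largest folds in hda9 lay in genes whose counts may have been divided with a neighbour or a copy. PAO2, a polyamine oxidase gene, had 0.09 counts in WT and 591 in hda9, but the upstream reading frame CPuORF17 beside it had 1045 and 314, and the sums were 1045 and 905. AT5G45430 had 268 and 1482 counts, and with CPuORF24 the sums were 1796 and 2154. CPuORF14 had 195 and 0 counts, and with AT5G52550 the sums were 387 and 410. AT1G25150 had 0 and 362 counts and has 4 near-identical copies, and with the measured genes there the sums were 1739 and 1682. MP3 had 266 counts in WT and 0 in hda9, while AT2G24945, the next gene in the table, had 281 and 412. Of 18663 genes compared, 272 were at least 2-fold higher and 328 lower. At a pseudocount of 0.1 these were 519 and 757. The balance turned at a pseudocount of 5, with 77 and 63, with an FPKM minimum of 5, with 194 and 165, and with libraries scaled by the median ratio, with 338 and 291.

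**Figure D1:**
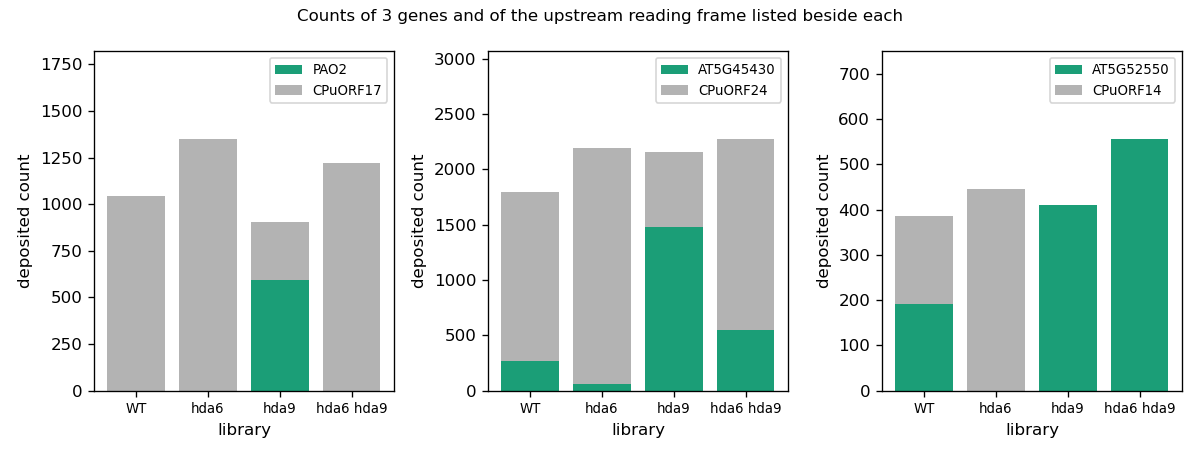
Stacked bars give the deposited counts (vertical axis) in each of the 4 libraries (horizontal axis) for PAO2, AT5G45430 and AT5G52550 in green and for the upstream reading frame listed beside each in grey. The division between green and grey differs between libraries more than the height of the bars, which is 1045, 1349, 905 and 1221 counts for PAO2 with CPuORF17.

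The double mutant was set beside WT to see what differed where both genes were mutated. Secondary wall and dehiscence genes were lower, with a median log2 fold of -0.50 over 23 genes (percentile 0), and 5 were at least 2-fold lower. CESA4 had a count ratio of 0.35 (0.327 to 0.373), CESA7 of 0.332 (0.306 to 0.359) and IRX12, a laccase gene, of 0.35 (0.323 to 0.379). In hda6 the ratios of CESA4, CESA7 and IRX12 were 0.492, 0.485 and 0.579. Auxin-related lists differed among themselves. GH3 genes had a median of 0.58 over 8 genes (percentile 100), with GH3.5 at 0.75 and GH3.17 at 0.84. Auxin transport genes had a median of 0.23 over 20 genes (percentile 99.84), with the efflux carrier genes PIN4 and PIN7 both at 0.52, and ARF genes 0.21 over 15 (percentile 99.11). Aux/IAA genes had a median of 0.05 over 25 (percentile 74.01), receptor genes 0.04 over 6 (percentile 66.12), and biosynthesis genes -0.04 over 11 (percentile 41.07). SAUR genes had a median of -0.01 over 45 genes (percentile 60.82), yet 9 members were at least 2-fold lower, among them SAUR64 at -1.48, SAUR68 at -1.38, SAUR62 at -1.20 and SAUR67 at -1.13. SAUR62 and SAUR67 each have a near-identical copy. In hda9 the SAUR list had a median of -0.18 over 47 genes (percentile 24.69), with 4 at least 2-fold lower and 1 higher. Counts in WT, hda9 and hda6 hda9 were 35, 22 and 9 for SAUR64 and 12, 2 and 0 for SAUR68. They were 54, 7 and 20 for SAUR62 and 41, 23 and 16 for SAUR67, so lower values were not particular to the double mutant. In hda6, SAUR64, SAUR68, SAUR62 and SAUR67 had 58, 20, 65 and 39 counts. Among the genes named here and above by the fixed rule, CESA4, CESA7, COR15B, CYCD3-2, AT5G16350 and AT5G60610 also overlap another gene. AT5G45570 has a near-identical copy. The values of these genes are uncertain to that extent.

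For cell wall growth in these whole siliques, EXPA3, an expansin gene, had 368 counts in WT and 893 in hda6 hda9, a ratio of 2.31 (2.04 to 2.62), against 1.12 (0.975 to 1.29) in hda6 and 0.939 (0.805 to 1.09) in hda9. EXPA21, another expansin gene, was lower, with 1746 counts in WT and 1008 in hda6 hda9 (1807 and 1091 with the overlapping AT5G39250). The expansin list as a whole had a median of 0.03 over 24 genes (percentile 61.59). Primary wall and growth genes had a median of 0.20 over 17 genes (percentile 99.19), with PRE2 at 19 and 51 counts and PME68 at 1392 and 818. Fruit patterning genes had a median of 0.18 over 17 (percentile 98.66), with YAB3 at 1.21 and SPT at 0.61. Flowering-time genes had a median of 0.41 over 14 (percentile 100), with SOC1 at 1.02. Senescence genes had a median of 0.32 over 13 (percentile 99.96), with SAG12 at 1.57. Stress genes had a median of 0.23 over 20 (percentile 99.9), with KIN2 at a ratio of 2.75 (2.47 to 3.07). This median was below the 0.44 in hda9, but set directly against hda9 the list had a median of 0.28 (percentile 99.96). In that direct comparison 3 stress genes were at least 2-fold higher and 2 lower. Jasmonate genes had a median of -0.31 over 19 (percentile 0), and TIFY9 was at -1.36. Cytokinin genes had a median of -0.03 over 18 (percentile 57.91), with CKX2 at -1.33 (452 and 209 counts with the overlapping RECA2), ARR4 at 180 counts in WT and 80 in hda6 hda9, and CKX3 at 7 and 32 counts. Pollen genes had a median of 0.21 over 17 (percentile 98.24). Reference genes had a median of 0.04 over 14 (percentile 57.37).

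Among the largest folds, AT5G26270, AT3G54730, AT3G01345, XLOC_007305, AT5G45570, AT2G19850 and AT2G05642 were higher in hda6 hda9 too, with log2 folds from 4.95 to 5.99. XLOC_007404 had 0 counts in WT, 345 in hda6, 0 in hda9 and 365 in hda6 hda9. LURP1, a gene of the response to pathogens, had 183 and 11 counts, a ratio of 0.0573 (0.0281 to 0.105), against 0.745 (0.597 to 0.928) in hda6 and 0.475 (0.36 to 0.621) in hda9. ROS1 had a ratio of 0.172 (0.154 to 0.192). PUX9 had 0 counts and with AT4G00750 a sum of 521, and AT5G38160, AT5G63250, AT3G24068 and AT5G05030 had log2 folds of -3.58, -3.46, -2.74 and -2.64. Of 18962 genes compared, 352 were at least 2-fold higher and 301 lower. At a pseudocount of 0.1 these were 679 and 617, and at 5 they were 77 and 76. The balance turned with an FPKM minimum of 5, with 152 and 173, and without XLOC loci, with 287 and 289.

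**Figure D2:**
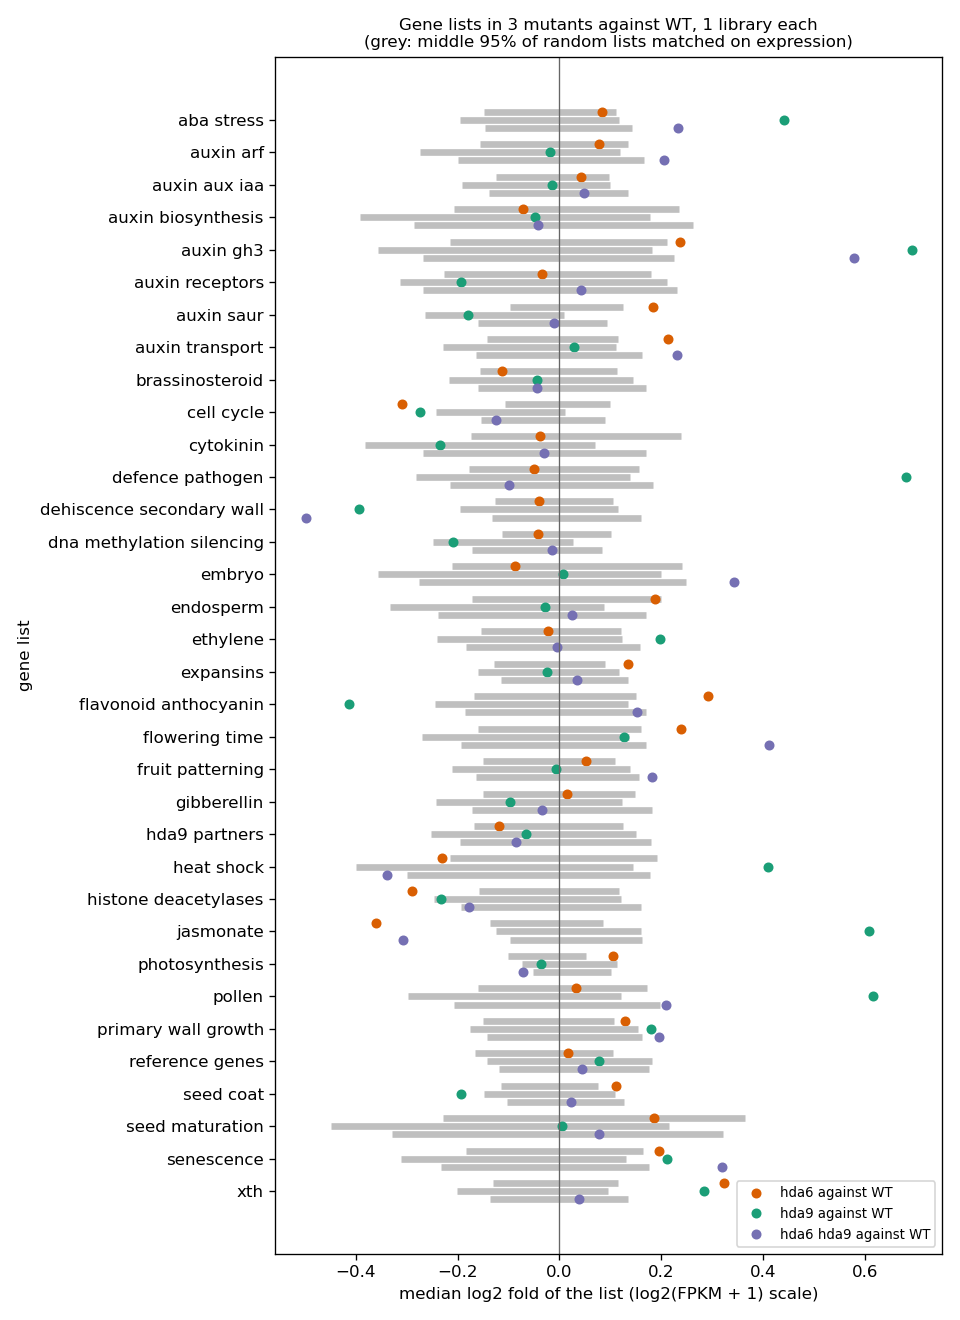
Each point is the median log2 fold of a gene list (horizontal axis, log2(FPKM + 1) scale) in hda6, hda9 or hda6 hda9 against WT, with 1 library each, and grey bars hold the middle 95% of random lists matched on expression. The jasmonate list lies at -0.36, 0.61 and -0.31, and the secondary wall list at -0.04, -0.39 and -0.50.

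Several lists described above for some of the mutants also stood outside the middle 95% of random lists in others. Xyloglucan endotransglucosylase/hydrolase genes were at 0.29 in hda9 (percentile 99.99), but at 0.04 in hda6 hda9 (percentile 70.7). Cell cycle genes were at -0.27 in hda9 (percentile 0.71), and inside that range at -0.13 in hda6 hda9 (percentile 6.46). Heat shock genes were at -0.23 in hda6 (percentile 1.68) and -0.34 in hda6 hda9 (percentile 0.95). GH3 genes were at 0.24 (percentile 98.46), flowering-time genes at 0.24 (percentile 99.76) and expansins at 0.14 (percentile 99.79) in hda6. Primary wall genes were at 0.13 in hda6 (percentile 99.05) and 0.18 in hda9 (percentile 98.69), and senescence genes at 0.20 (percentile 98.71) and 0.21 (percentile 99.54). Of the lists not described, 5 stood outside it. Seed coat genes were at 0.11 in hda6 (percentile 99.65) and -0.19 in hda9 (percentile 0.36), and histone deacetylase genes at -0.29 in hda6 (percentile 0.02). Ethylene genes were at 0.20 in hda9 (percentile 99.62), embryo genes at 0.34 in hda6 hda9 (percentile 99.48) and photosynthesis genes at 0.10 in hda6 (percentile 99.96) and -0.07 in hda6 hda9 (percentile 0.88).

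The double mutant was then set beside hda6. Cell cycle genes were higher in hda6 hda9, with a median log2 fold of 0.15 over 40 genes (percentile 100), and secondary wall genes were lower, at -0.39 over 22 genes (percentile 0). SAUR genes had a median of -0.23 over 47 genes (percentile 0.09), and 11 were at least 2-fold lower. AT4G23680 had 27 counts in hda6 and 132 in hda6 hda9, and RPL30A had 5 and 31. Pollen genes had a median of 0.46 over 16 genes (percentile 100), which was -0.1347 with an FPKM minimum of 5. AT5G41660 had 562 counts in hda6 and 15 in hda6 hda9, XLOC_001802 had 353 and 1, and XLOC_001776 had 66 and 1. AT5G41660, XLOC_001802 and XLOC_001776 each had 0 counts in WT, and 0, 0 and 2 in hda9. Their high values were therefore seen in the hda6 library only, and did not recur in hda6 hda9, where HDA6 was mutated too. AT5G52550, CPuORF14 and AT5G45430 also came out among the largest folds, and their counts may have been divided with a neighbour as described above. Of 19034 genes compared, 134 were at least 2-fold higher and 242 lower. At a pseudocount of 0.1 these were 329 and 603, and at 5 they were 21 and 53.

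Against hda9, the double mutant had lower jasmonate genes, with a median log2 fold of -0.97 over 20 genes (percentile 0) and 10 at least 2-fold lower, and TIFY9 had 1273 counts in hda9 and 178 in hda6 hda9. Defence genes had a median of -0.71 over 13 genes and heat shock genes -0.72 over 9, both at percentile 0. Pollen genes were lower beside them, with a median of -0.25 over 18 genes (percentile 0.04) and 5 of the 18 above 0. Flavonoid and anthocyanin genes had a median of 0.61 over 16 genes (percentile 100), and 4 were at least 2-fold higher. UGT75C1 had 18 and 166 counts (183 and 388 with the overlapping AT4G14100) and MYB90 had 18 and 104. AT3G01345, AT5G26270, AT2G19850 and AT3G54730 had at most 3 counts in hda9 and 2060, 840, 651 and 761 in hda6 hda9. PUX9 had 174 counts in hda9 and 0 in hda6 hda9, and with AT4G00750 the sums were 1574 and 521. Of 18754 genes compared, 382 were at least 2-fold higher and 326 lower, but the balance turned with libraries scaled by the median ratio, with 352 and 375, at a pseudocount of 5, with 86 and 176, with an FPKM minimum of 5, with 162 and 263, and without XLOC loci, with 312 and 324.

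The genes at least 2-fold different were then compared between mutants, among genes counted in both comparisons. Between hda6 and hda6 hda9, 221 genes were higher in both, and 90 were lower in both. Between hda9 and hda6 hda9, 44 were higher in both and 140 lower in both. Between hda6 and hda9, 30 were higher in both, 66 lower in both, and 12 differed in opposite directions. Independent lists of these sizes would share 5.73, 2.23, 2.34, 5.34, 2.52 and 2.47 genes in the same order. All 3 comparisons used the same WT library, which alone makes lists overlap, and part of the excess may come from it because a lone WT library cannot be split. Unchanged libraries simulated against 1 WT library shared 10.5, 14.6, 10.7, 14.7, 10.7 and 13.5 genes with normal noise. With heavier-tailed noise (a t distribution with 3 degrees of freedom) of the same robust spread they shared 117, 140, 117, 139, 116 and 140, so only the 221 genes higher in hda6 and hda6 hda9 lay above both simulations, and the 140 lower in hda9 and hda6 hda9 lay level with the second. The simulated libraries had 157 genes at least 2-fold different per comparison with normal noise and 783 with heavier-tailed noise, against 603 observed, so neither noise describes the libraries well.

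Of the 352 genes at least 2-fold higher in hda6 hda9, 201 were also at least 2-fold higher in hda6 but not hda9, 24 in hda9 but not hda6, 20 in both and 107 in neither. Of the 301 lower, 31 were also lower in hda6 but not hda9, 81 in hda9 but not hda6, 59 in both and 130 in neither. Unchanged libraries simulated as above had 59.0 higher and 54.1 lower genes in neither single mutant with normal noise, and 237 and 217 with heavier-tailed noise. The log2 fold of the double mutant minus the sum of the folds of both single mutants had a median of -0.11 over the higher genes and 0.23 over the lower genes. The double mutant exceeded that sum by 2-fold or more in its own direction in 21 higher and 25 lower genes, against 6.76 and 3.72 in unchanged libraries with normal noise and 106 and 86.5 with heavier-tailed noise. These counts lay between both simulations, over genes chosen for a large fold in the double mutant and with the WT library shared by all folds, so they do not measure a combined effect. EXPA3 had log2 folds of 0.16, -0.09 and 1.18 in hda6, hda9 and hda6 hda9, and LURP1 had -0.38, -0.89 and -3.26.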

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

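Among the tests in this part, those of thinning, of near-identical copies of the 111 loci and of chromosome 5 were stated before their results were seen, and the others were chosen after. For 4 gene lists hda6 and hda9 stood on opposite sides of the random lists, and these differences were not tested, since each mutant had 1 library. The median log2 fold of hda9 minus that of hda6 was 0.97 for jasmonate genes, 0.64 for heat shock genes, -0.705 for flavonoid and anthocyanin genes, and -0.304 for seed coat genes.

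Jasmonate, defence and heat shock genes together had a median log2 fold of 0.53 over 42 genes in hda9, against -0.22 in hda6. In hda6 hda9 the median was -0.2524 (95% interval of the median over genes -0.39 to -0.08) with pollen genes at percentile 98.24 against WT, while against hda9 pollen genes were lower together with the 3 lists. Against WT, defence genes alone had medians of -0.05 in hda6 (percentile 29.9) and -0.10 in hda6 hda9 (percentile 19.4). Both lay inside the middle 95% of random lists. A loss of HDA9 that acts whatever the state of HDA6 was taken to predict a value above 0 there. The -0.2524 was set against WT, however, and so includes any effect of the hda6 mutation. Set against hda6 instead, hda6 hda9 had medians of 0.10 for jasmonate genes (percentile 67.16), -0.12 for defence genes (percentile 11.4) and -0.02 for heat shock genes (percentile 59.14). These lay inside the middle 95% of random lists. Each genotype had 1 library, so such a loss stays open. Pollen or stamen RNA was also taken to predict a value above 0, because pollen genes were higher in hda6 hda9 too. Such RNA in the hda9 library sets no value in another library, however, so the -0.2524 does not test it, and it stays open. Handling of the hda9 tissue at harvest cannot be told apart from the genotype, because there was 1 hda9 library. An effect of HDA9 that needs HDA6 also stays open and was not tested.

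At 111 loci WT had at most 3 reads and hda6 had at least 30, and 59 of them were XLOC loci. The library totals were 12758490 counts in hda6 and 11362313 in WT, too small a difference in depth to bring a locus from 3 reads to 30. Thinning the hda6 counts to the WT total could therefore remove only loci just above 30 reads, and 101 loci kept 30. Of the 52 found in the reference, 10 lay on chromosome 5, where HDA6 lies (19.2%, exact 95% interval 9.63 to 32.5%, against 23.4% of measured genes), which argues against a linked parental segment as the source of most of them. Near-identical copies were found for 15 of the 52, so for these the reads may come from another copy, and the XLOC loci could not be searched. In hda6 hda9, 73 of the 111 also had 30 reads, and in hda9 1 did. A hypothesis of derepression on loss of HDA6 would need such a pattern. The rest of the 111 fell short of 30 reads in hda6 hda9, although HDA6 was mutated there too. Among them, AT5G41660 had 562 counts in hda6 and 15 in hda6 hda9, and XLOC_001802 had 353 and 1. Loss of HDA6 alone would not predict these values, each from 1 library, and any other difference carried by the hda6 line stays open.

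Between WT and hda9, 23 genes had at most 3 reads in 1 library and at least 30 in the other. Of the 21 found in the reference, 6 overlap another gene, and pooling left 3 of these under 2-fold, while 9 of the 23 overlap a gene or have a neighbour absent from the reference, such as CPuORF17 beside PAO2, and pooling left 6 under 2-fold, so divided counts may account for some of the genes. Pooling can hide a real change beside an abundant neighbour, and it did not cover neighbours that the reference lists without overlap, such as AT2G24945 beside MP3. Near-identical copies were found for 1 of the 21, AT1G25150, which argues against copies as the source of most. In hda6 hda9, 13 of the 23 stood on the same side as in hda9, but 8 of these 13 also did in hda6, where HDA9 was not mutated, and the shared WT library could place genes there too, so a loss of HDA9 stays open.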

How the results depend on the processing

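WT was identical in the 3 tables, so averaging it changed nothing and was not run, and no authors' table of the double mutant against a single mutant was used here, so their fold and false discovery rate gave no value there. No paired analysis was possible because each genotype had 1 library. The counts of genes stayed within 1.5 times the reported value under both scalings, CPM, the authors' false discovery rate, and the 3 alternatives chosen after seeing the data. With no filter the counts were identical, which was fixed in advance. A 2-fold difference at a pseudocount of 1 already needs an FPKM of 1 or more in 1 of the 2 libraries. Median-ratio scaling nevertheless turned the balance of higher and lower genes in hda9 (338 and 291) and in hda6 hda9 against hda9 (352 and 375). The counts moved with the pseudocount and the FPKM minimum, as larger pseudocounts shrink folds of low genes and a higher minimum leaves fewer genes. In the order hda6, hda9 and hda6 hda9 against WT, then hda6 hda9 against hda6 and against hda9, a pseudocount of 0.1 gave 787, 519, 679, 329 and 818 genes higher and 324, 757, 617, 603 and 522 lower. A pseudocount of 5 gave 95, 77, 77, 21 and 86 higher and 23, 63, 76, 53 and 176 lower. An FPKM minimum of 5 gave 185 higher and 70 lower in hda6, 165 lower in hda9, 152 higher and 173 lower in hda6 hda9, 78 higher and 140 lower against hda6, and 162 higher against hda9. The authors' deposited fold gave 841, 554 and 725 higher and 365, 845 and 672 lower in the 3 mutants. Of the list medians, 1006 alternatives stayed within the spread of the list, 8 moved and 1 reversed, pollen genes in hda6 hda9 against hda6, which were at 0.46 and at -0.1347 with the FPKM minimum of 5. The cause was not tested. Of the values of named genes, 2898 kept their side of 2-fold and 117 did not, and none reversed. Of the overlaps, 18 stayed within 1.5 times and 18 moved.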

Other observations

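Pathways of the deposited annotation, looked at after the gene lists, gave further groups (101 pathways with at least 15 measured genes, each against 2000 random lists). Ribosome biogenesis genes were lower in all 3 mutants, with median log2 folds of -0.20 in hda6, -0.30 in hda9 and -0.26 in hda6 hda9, each at percentile 0. Pyrimidine metabolism genes had medians of -0.13, -0.20 and -0.13. DNA replication genes had medians of -0.28, -0.18 and -0.13 in the same order (percentiles 0, 11.9 and 4.85) and mismatch repair genes -0.25, -0.24 and -0.19 (percentiles 0, 2.8 and 1.05). Oxidative phosphorylation genes were higher in all 3 mutants, with medians of 0.04, 0.10 and 0.21 (percentiles 99.2, 99.85 and 100). Fatty acid metabolism genes had a median of -0.17 in hda9 (percentile 0), against 0.02 in hda6 and 0.01 in hda6 hda9. Since all comparisons shared 1 WT library, a value particular to that library would appear in all 3 mutants.

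QQS, an orphan gene linked to starch content and chosen after its values were seen, had 34 counts in WT, 417 in hda6, 1 in hda9 and 242 in hda6 hda9. Seed maturation genes had median log2 folds of 0.19 over 10 genes in hda6, 0.01 over 8 in hda9 and 0.08 over 9 in hda6 hda9 (percentiles 83.47, 78.53 and 72.29), and members differed in direction. The seed gene NFYB9, also known as LEC1, had 45, 14, 4 and 5 counts, and WRI1, a regulator of seed oil synthesis, had 124, 60, 80 and 57, while ABI5 had 115, 124, 83 and 154 and OL3 had 7, 13, 3 and 19.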
